A study of Mus musculus with 54 samples.

How the data were processed

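The 54 libraries were poly(A) RNA sequencing of mouse samples in 17 groups: 24 libraries of primary lung fibroblasts in 8 groups, and 30 of whole lungs from male C57BL/6 mice in 9 groups of 3 experiments. Samples were grouped by their titles and characteristics in the labels. The deposited values are 4 tables of TPM, a transcript share scaled to a fixed total, made by the authors over all genes of each table, with 1 column per sample. Per the submitters' processing notes, the genome build was mm39, and FastQC, Trim Galore, HISAT2, featureCounts, Subread and DESeq2 were used, without versions, roles or order. The annotation is not given in the sources used here. Read counts were not used here, so the sequencing depth of each sample and the counting error of each value are unknown, and no interval for counting error is given. The labels describe RNA extraction from cells and from heart tissue, while every whole-tissue sample is labelled as lung. Fibroblasts and mice are labelled as batches 1 to 4, 1 for the cultures and 1 for each mouse experiment, so none of the 14 comparisons crosses batches, while levels and effects set side by side between experiments do. Nothing in the sources used here says that the replicate numbers pair samples.

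Values on genes without a symbol (0.212 to 0.367% of TPM in the lung tables) were left out, and values listed more than once under a symbol (27 to 29 entries per lung table) were added. The fibroblast table lists 26264 genes and no mitochondrial transcripts. Genes with a TPM of at least 1 in at least 3 libraries of a table were tested: 13084 in fibroblasts, 17209 in the water experiment, 18593 in the diet experiment and 18151 in the BT2 experiment. Values were taken as log2(TPM + 1), a pseudocount of 1. Each table was fitted with group means in limma 3.58.1 (R 4.3.3), with a mean-variance trend, because groups hold only 3 or 4 libraries, and 14 comparisons were made. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. Each adjusted p of a gene is from limma. A TPM is a share of its library, so each count of changed genes was also made after each library was centred on its median log2 ratio to the mean library.

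The 17 gene lists and 17 cell type marker lists, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over all lists of a comparison, and again with an estimated correlation. Members were also adjusted over the list alone. By the rule, named genes were, in each comparison, the 4 largest rises and 4 largest falls among passing genes with a mean TPM of at least 5 in a compared group and no overlap between the groups' libraries. To these came the 3 passing members with the largest change of each list past the camera threshold, and 12 fixed genes, among them Col1a1, Acta2, Timp1, Bcat1 and Asns. Predicted genes, pseudogenes, mitochondrial genes and receptor segments were left out. The text has room for part of these, and that part was chosen after the values were seen; some genes named by the rule are not reported here. Some genes have near-identical copies between which reads are uncertain: Hspa1a and Hspa1b, haemoglobin, lysozyme and ribosomal protein genes.

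Genes that bleomycin moved by at least 1 log2 in the same direction in both other experiments were tested in each treated group. Effects that share libraries were correlated across genes beside a simulation with unchanged groups and the same shared libraries. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a TPM of 5, median centring, a fit of only the compared groups, array weights, the replicate number as a block, and each library left out in turn. Removal of each library's trend with GC content and transcript length (from a GRCm38 annotation, for 97.4 to 99.3% of tested genes), the list counts without single libraries that stood apart, and the alternatives for correlations and overlaps were added after the data were seen. The procedure was tested on data simulated from these libraries, with 200 changed genes in each of 5 runs. It recovered 90.2% of 2-fold changes for BCAA removal under TGF-β1, 61% with BCAA in water, 61.4% with the BCAA-free diet and 44.2% with BT2. Of the simulated calls 4.5 to 5.87% were false, which is no estimate for the real ones. The PBS groups with BCAA or BCKA returned entered the fibroblast fit but none of the 14 comparisons, and the group with BCKA also served to choose genes moved by TGF-β1 for a further test.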

Results

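Poly(A) RNA was sequenced from 54 mouse samples in 17 groups, to ask how branched-chain amino acids (BCAA: leucine, isoleucine and valine) and their keto acids (BCKA) bear on fibroblast activation and on bleomycin lung injury. In cell culture, 24 libraries of primary lung fibroblasts came from 8 groups of 3. Cells spent 24 h in complete medium, in medium free of BCAA, or in the free medium with BCAA or BCKA returned, and then 48 h with PBS or with 20 ng/mL of transforming growth factor β1 (TGF-β1), which turns fibroblasts into matrix-secreting myofibroblasts. Whole lungs came from 3 mouse experiments, each with a PBS group, a bleomycin group and a treated bleomycin group. In the water experiment (3 mice per group) bleomycin was given at 1.25 mg/kg, BCAA at 3 mM in drinking water from 7 days before, and lungs were taken on day 14. The diet experiment (4 mice per group) used 1.25 mg/kg and a BCAA-free diet from day 7 for 14 days, with lungs taken on day 21. The BT2 experiment (3 mice per group) used 3.5 mg/kg and daily injections from day 3 for 11 days of 10% DMSO or of 20 mg/kg BT2, an inhibitor of the kinase that switches off BCKA oxidation, with lungs taken on day 14. The deposited values are TPM only, so the sequencing depth of each sample is unknown. Genes listed above 0 numbered 15003 to 16653 per fibroblast library, 23019 to 24819 in the water experiment, 17554 to 25632 in the diet experiment and 23653 to 25628 in the BT2 experiment. Mitochondrial transcripts made up 6.85 to 14.4% of TPM in the water experiment, 4.38 to 17.3% in the diet experiment and 3.67 to 6.37% in the BT2 experiment, while the fibroblast table lists none. Levels below are mean TPM ± SD (SD, n = 3 per group, or n = 4 in the diet experiment), the treated group first. Fold changes, written as log2, are on the log2(TPM + 1) scale. Genes are given by the symbols in the tables, which hold no identifiers or positions. Genes said to rise or fall most do so among those with a mean TPM of at least 5 in a compared group and no overlap between the groups' libraries. Members of a gene list not counted as rising or falling did not pass, and the adjusted p of a list is from camera. Counts adjusted over the list alone are given where they differ from those over all genes. With an estimated instead of a preset correlation, 9 of 19, 5 of 12, 10 of 13, 9 of 15, 10 of 13, 10 of 14, 2 of 10 and 0 of 12 list calls held in the 8 fibroblast comparisons, in the order given, and 0 of 22, 24, 19, 22, 17 and 18 in the lung comparisons. Beside each call that was lost, the adjusted p with an estimated correlation is given as the estimated-correlation p.

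The first comparison asks what TGF-β1 does to fibroblasts in complete medium. The secreted binding protein Igfbp2 (508 ± 138 against 4.95 ± 0.719 TPM, 6.39 log2, adjusted p = 4.05e-15) rose most. It was followed by the neuropeptide precursor Vgf (115 ± 16.2 against 0.775 ± 0.196 TPM, 6.02 log2, adjusted p = 4.36e-17) and by skeletal actin, Acta1 (69.1 ± 7.55 against 0.211 ± 0.0338 TPM, 5.85 log2, adjusted p = 7.17e-20). Periostin, a matricellular protein of scar tissue, rose as well, Postn (1467 ± 29 against 28.9 ± 1.57 TPM, 5.62 log2). Complement component C7 (3.39 ± 1.14 against 258 ± 14.4 TPM, -5.92 log2, adjusted p = 4.35e-15) fell most. The B cell chemokine Cxcl13 (1.46 ± 0.433 against 112 ± 4.46 TPM, -5.53 log2, adjusted p = 4.11e-18) fell too. Of the contractile and myofibroblast genes, 16 of 23 rose, with a median of 0.75 log2, adjusted p = 1.69e-12. Examples were smooth muscle actin, Acta2 (2358 ± 475 against 696 ± 12.9 TPM, 1.74 log2), calponin, Cnn1 (146 ± 18.8 against 24.1 ± 0.173 TPM, 2.54 log2), and the collagen receptor subunit Itga11 (3.69 log2). Pericyte and smooth muscle markers moved with them (7 of 9 rose, adjusted p = 1.26e-08). Of the extracellular matrix genes, 20 of 41 rose and 13 fell, with a median of 0.72 log2, adjusted p = 9.09e-06, estimated-correlation p = 0.0684. Type I collagen Col1a1 (23480 ± 1570 against 4658 ± 273 TPM, 2.33 log2) and elastin Eln (5.07 log2) rose, whereas decorin, Dcn (-3.51 log2), fell. Col3a1 (7687 ± 527 against 10170 ± 309 TPM, adjusted p = 0.266) and Fn1 (8657 ± 3080 against 10660 ± 1300 TPM, adjusted p = 0.266) did not pass. Of the TGF-β1 response genes, 16 of 29 rose and 6 fell, with a median of 0.70 log2, adjusted p = 1.36e-06, estimated-correlation p = 0.0917. The matricellular Ccn2 (1060 ± 22.9 against 109.6 ± 6.6 TPM, 3.26 log2) and Ccn4 (2.92 log2) were among them. Collagen crosslinking genes followed (15 of 24 rose and 3 fell, 15 and 4 adjusted over the list alone, adjusted p = 4.5e-09), among them Lox (1.78 log2) and Loxl3 (2.64 log2).

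Sterol and fatty acid synthesis genes rose together: 22 of 27 rose, with a median of 1.08 log2, adjusted p = 2.28e-20, as in Fdps (1.69 log2). Of the glycolysis genes, 16 of 21 rose and 1 fell, 17 and 1 adjusted over the list alone, with a median of 0.82 log2, adjusted p = 5.76e-14, as in the lactate exporter Slc16a3 (1.61 log2). Genes of the amino acid shortage response, the programme run by ATF4, also rose (23 of 36 rose and 6 fell, 23 and 7 adjusted over the list alone, adjusted p = 6.77e-10). Asparagine synthetase, Asns (128 ± 24.9 against 32.7 ± 2.26 TPM, 1.92 log2), and the pseudokinase Trib3 (19.9 ± 4.71 against 4.02 ± 0.31 TPM, 2.04 log2) were among them. The cytosolic transaminase for BCAA, Bcat1 (51.4 ± 3.49 against 13.7 ± 1.57 TPM, 1.84 log2), rose, while Bckdk, the kinase of the keto acid dehydrogenase, stood at 69.3 ± 5.9 against 69 ± 3.72 TPM (adjusted p = 0.977). Alveolar and adventitial fibroblast markers fell (11 of 12 fell, a median of -1.75 log2, adjusted p = 2.21e-08), as in Scara5 (-4.08 log2) and Inmt (2.56 ± 0.457 against 69.4 ± 6.53 TPM, -4.31 log2). Of the interferon response genes, 23 of 31 fell, 24 adjusted over the list alone, with a median of -0.99 log2, adjusted p = 0.000224, estimated-correlation p = 0.281. Of the p53 targets, 10 of 22 rose and 4 fell (adjusted p = 0.000224), led by Cdkn1a (1.33 log2). Mesothelium markers fell in 5 of 5 (adjusted p = 0.00271). Of cell division genes, 1 of 36 rose and 23 fell, 1 and 25 adjusted over the list alone, with a median of -0.51 log2, adjusted p = 0.0404, estimated-correlation p = 0.371. This call was lost without Complete_PBS replicate 2 (adjusted p = 0.102), Complete_TGFb replicate 1 (0.061) or Complete_TGFb replicate 3 (0.0555). In all, 6357 of 13084 genes passed, 1590 higher and 4767 lower. With each library centred on its median the split was 2789 higher and 3010 lower, since centring moved the median of all genes by -0.193 log2. Nothing in the sources used here says that replicates were separate cultures, and if they were not, each p measures only the spread between these samples.

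Removal of BCAA without TGF-β1 was compared next. Cell division genes rose: 19 of 36 rose, 25 adjusted over the list alone, with a median of 0.75 log2, adjusted p = 1.78e-49. The kinetochore protein Cenpf (15.8 ± 0.537 against 5.68 ± 0.438 TPM, 1.33 log2, adjusted p = 0.000525) and the spindle protein Aspm (10.6 ± 1.21 against 4.08 ± 1.05 TPM, 1.20 log2, adjusted p = 0.00351) were among them. So were the proliferation marker Mki67 (35.4 ± 2.87 against 16 ± 1.44 TPM, 1.10 log2, adjusted p = 0.00265) and Ckap2l (1.28 log2). The heparin-binding plasma protein Clec3b (3.82 ± 1.49 against 13.5 ± 0.285 TPM, -1.63 log2, adjusted p = 5.96e-06) and the haem-degrading enzyme Hmox1 (57.1 ± 3.39 against 107 ± 11.2 TPM, -0.89 log2, adjusted p = 0.00334) fell. Interferon response genes were lower as a group (2 of 31 fell, 22 adjusted over the list alone, a median of -0.51 log2, adjusted p = 9.24e-24), with Ifi27l2a (-1.47 log2) and the GTPase Igtp (-0.61 log2). Fibroblast markers fell in part (3 of 12 fell, 5 adjusted over the list alone, a median of -0.37 log2, adjusted p = 1.95e-07). They included Gsn (-0.75 log2), Inmt (37.8 ± 1.94 against 69.4 ± 6.53 TPM, -0.86 log2) and Dpt (-0.75 log2). Mesothelium markers moved the same way (1 of 5 fell, 5 adjusted over the list alone, adjusted p = 5.28e-08), with Upk3b (-0.71 log2). Pericyte and smooth muscle markers went up (1 of 9 rose, 4 adjusted over the list alone, adjusted p = 9.53e-06). Smooth muscle actin was the member that passed, Acta2 (1133 ± 78 against 696 ± 12.9 TPM, 0.70 log2, adjusted p = 0.0353). Of 36 genes of the amino acid shortage response none passed under limma (3 rose adjusted over the list alone), and 6 were higher and 2 lower at an unadjusted p under 0.05. Asns, asparagine synthetase, stood at 48.3 ± 5.45 against 32.7 ± 2.26 TPM (adjusted p = 0.115) and Bcat1 at 18.9 ± 1.12 against 13.7 ± 1.57 TPM (adjusted p = 0.147). Of the matrix genes none passed under limma (2 fell adjusted over the list alone), with 3 higher and 3 lower of 41 at an unadjusted p under 0.05. Col1a1 stood at 4500 ± 450 against 4658 ± 273 TPM. In total 119 genes passed, 75 higher and 44 lower. The count was 38 to 88 without single libraries. The call of transitional epithelium markers (adjusted p = 0.0102, estimated-correlation p = 0.058) ended without Free_PBS replicate 3 (0.066). Of the 13 genes named as changed, Acta2 lost its call without any 1 of the 6 libraries, and Igtp without any but Free_PBS replicate 2. Upk3b lost it without Complete_PBS replicate 1 or 2 or Free_PBS replicate 2 or 3, and Ifi27l2a without Complete_PBS replicate 1. Adjusted p ran from 0.0523 to 0.174 in these cases.

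The main culture question was what TGF-β1 treated fibroblasts lose or gain without BCAA. The transmembrane protein Tenm4 (93.5 ± 21.1 against 0.274 ± 0.2 TPM, 6.20 log2, adjusted p = 2.55e-18) and the adrenergic receptor Adra2a (57.3 ± 0.961 against 0.219 ± 0.097 TPM, 5.58 log2, adjusted p = 1.27e-18) rose most. Skeletal actin Acta1 (0.8 ± 0.199 against 69.1 ± 7.55 TPM, -5.28 log2, adjusted p = 2.09e-19) fell most. The hyaluronan-degrading protein Cemip (70.7 ± 3.24 against 2862 ± 824 TPM, -5.27 log2, adjusted p = 5.27e-17) and the integrin Itga8 (2.17 ± 0.896 against 112 ± 24 TPM, -5.17 log2, adjusted p = 7.8e-16) followed. The contractile programme was lower: 1 of 23 rose and 19 fell, with a median of -1.25 log2, adjusted p = 2.1e-11. Smooth muscle actin fell, Acta2 (160.5 ± 48.6 against 2358 ± 475 TPM, -3.90 log2), as did leiomodin, Lmod1 (-4.40 log2), and Cnn1 (7.6 ± 3.4 against 146 ± 18.8 TPM, -4.18 log2). Matrix genes were also lower (2 of 41 rose and 27 fell, a median of -1.01 log2, adjusted p = 1.41e-09). They included fibromodulin Fmod (-4.77 log2), the repair-associated Cthrc1 (3.43 ± 0.992 against 104 ± 15.7 TPM, -4.58 log2) and thrombospondin Thbs1 (1630 ± 524 against 15830 ± 3620 TPM, -3.31 log2). Further falls were seen in Timp1 (368 ± 142 against 1355 ± 336 TPM, -1.93 log2) and in Col1a1 (12740 ± 13000 against 23480 ± 1570 TPM, -1.37 log2). Col3a1 (7076 ± 5790 against 7687 ± 527 TPM, adjusted p = 0.227), Fn1 (adjusted p = 0.416) and Ccn2 (adjusted p = 0.326) did not pass. Col3a1 did without Free_TGFb replicate 1 (-1.05 log2, adjusted p = 2.2e-08) and Fn1 without Complete_TGFb replicate 2 (-0.595 log2, adjusted p = 0.0468). Collagen processing genes followed (2 of 24 rose and 19 fell, adjusted p = 8.34e-09). Of the matrix proteases and inhibitors, 6 of 26 rose and 16 fell, with a median of -0.76 log2, adjusted p = 0.000493, estimated-correlation p = 0.145, and tissue plasminogen activator Plat (-3.24 log2) fell.

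Sterol and fatty acid synthesis genes fell together: 23 of 27 fell, with a median of -2.15 log2, adjusted p = 2.17e-17, as in Nsdhl (-3.05 log2) and Scd2 (229 ± 17.1 against 1724 ± 149 TPM, -2.91 log2). In the opposite direction, the amino acid shortage response rose (31 of 36 rose and 1 fell, a median of 1.20 log2, adjusted p = 1.32e-10). Examples were Trib3 (240.3 ± 85.1 against 19.9 ± 4.71 TPM, 3.49 log2), the stress transcription factor Ddit3 (186 ± 68 against 16.8 ± 5.64 TPM, 3.37 log2) and the cationic amino acid transporter Slc7a3 (3.37 log2). Cytosolic aminoacyl-tRNA synthetases, which charge tRNA with amino acids, rose almost throughout (19 of 20 rose, a median of 1.41 log2, adjusted p = 1.68e-10), as in Aars (2.00 log2) and Yars (2.00 log2). Chemokines and cytokines fell (2 of 18 rose and 14 fell, adjusted p = 6.59e-05), as in Cxcl12 (-2.62 log2), and interferon response genes fell in 20 of 31 (adjusted p = 0.000182, estimated-correlation p = 0.335). Bcat1 (1.39 log2) rose and the keto acid dehydrogenase phosphatase Ppm1k (-0.89 log2) fell. Fibroblast markers (11 of 12 fell, adjusted p = 7.87e-09) and mesothelium markers (5 of 5 fell, adjusted p = 0.00102) fell beside these groups. The TGF-β1 response list split (15 of 29 rose and 10 fell, 16 and 10 adjusted over the list alone), with a median of 0.39 but a camera direction of down (adjusted p = 0.989). Of 13084 genes 7895 passed, 4648 higher and 3247 lower, 1218 and 1154 of them by at least 2-fold. Centring moved the median of all genes by 0.106 log2, and after centring 3945 were higher and 3961 lower. Free_TGFb replicate 1 stood apart, with Col1a1 at 27680 TPM against 4495 and 6052 in replicates 2 and 3 and Rpl31, chosen after its values were seen, at 15.2 against 573 and 352. Without it 31 of 41 matrix genes, 18 of 23 contractile genes and 23 of 27 sterol genes fell, and 32 of 36 shortage genes and 20 of 20 synthetases rose.

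Whether the response to TGF-β1 itself differed without BCAA was tested as a difference of responses. It was lower for Acta1 (-5.35 log2), Cemip (-5.24 log2), Cnn1 (-4.83 log2) and Acta2 (-4.60 log2), among others, and higher for Tenm4 (6.33 log2), Ddit3 (3.43 log2) and Trib3 (3.22 log2). Acta2 reached 2358 ± 475 against 696 ± 12.9 TPM with TGF-β1 in complete medium, but 160.5 ± 48.6 TPM in free medium, where it stood at 1133 ± 78 TPM under PBS. For contractile genes, 1 of 23 rose and 18 fell, 1 and 20 adjusted over the list alone, with a median of -1.34 log2, adjusted p = 3.37e-14. Matrix genes (2 of 41 rose and 24 fell, adjusted p = 1.18e-09) included Cthrc1 (-4.72 log2) and Thbs1 (-3.09 log2). Responses of sterol genes (23 of 27 fell, adjusted p = 9.05e-21), such as Nsdhl (-3.12 log2), and of chemokines (1 of 18 rose and 13 fell, adjusted p = 1.89e-05), such as Cxcl12 (-2.55 log2), were lower too. Amino acid shortage genes (31 of 36 rose and 1 fell, 32 and 1 adjusted over the list alone, adjusted p = 9.98e-11) and tRNA synthetases (18 of 20 rose, 19 adjusted over the list alone, adjusted p = 1.37e-10) responded more. The stress transcription factor Atf3 (3.17 log2), Aars (2.06 log2) and Wars (2.37 log2) were examples. Of cell division genes, 4 of 36 rose and 27 fell, with a median of -0.95 log2, adjusted p = 1.89e-05, estimated-correlation p = 0.0798, as in the cyclin Ccnb2 (-2.00 log2). The replication genes Mcm2 (2.34 log2) and Mcm7 (2.11 log2) were higher. Timp1 (-1.99 log2), Ppm1k (-0.69 log2) and Bcat1 (0.95 log2) also differed. In total 6225 genes passed, 3820 with a higher and 2405 with a lower response, or 3069 and 3058 after centring. Centring moved the median by 0.118 log2.

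Returning BCAA to the free medium under TGF-β1 asked whether the losses could be undone. Acta1 (83 ± 5.01 against 0.8 ± 0.199 TPM, 5.55 log2, adjusted p = 1.4e-19), Cemip (2986 ± 342 against 70.7 ± 3.24 TPM, 5.37 log2, adjusted p = 3.77e-17) and Itga8 (115 ± 9.03 against 2.17 ± 0.896 TPM, 5.23 log2, adjusted p = 6.21e-16) rose. Both Tenm4 (0.248 ± 0.0627 against 93.5 ± 21.1 TPM, -6.22 log2, adjusted p = 2.99e-18) and Adra2a (0.24 ± 0.208 against 57.3 ± 0.961 TPM, -5.57 log2, adjusted p = 1.34e-18) fell. Contractile genes rose (19 of 23 rose and 1 fell, 21 and 1 adjusted over the list alone, a median of 1.35 log2, adjusted p = 4.98e-12). Examples were Acta2 (2278 ± 194 against 160.5 ± 48.6 TPM, 3.86 log2) and the collagen receptor subunit Itga11 (3.89 log2). Matrix genes rose (27 of 41 rose and 2 fell, 28 and 2 adjusted over the list alone, a median of 1.09 log2, adjusted p = 1.09e-09). Cthrc1 (91.4 ± 4.69 against 3.43 ± 0.992 TPM, 4.41 log2), Thbs1 (18090 ± 1550 against 1630 ± 524 TPM, 3.53 log2) and the protease inhibitor Timp1 (1179 ± 74.2 against 368 ± 142 TPM, 1.76 log2) rose. For Col1a1 (21710 ± 724 against 12740 ± 13000 TPM, 1.25 log2) the gain was smaller than the spread between the Free_TGFb libraries, and its call ended without Free_TGFb replicate 2 (adjusted p = 0.0601). Sterol genes rose (23 of 27 rose, 25 adjusted over the list alone, a median of 2.21 log2, adjusted p = 5.98e-18), as in Scd2 (1750 ± 68.5 against 229 ± 17.1 TPM, 2.93 log2). Shortage genes fell (1 of 36 rose and 32 fell, 1 and 33 adjusted over the list alone, a median of -1.31 log2, adjusted p = 4.06e-12). Both Trib3 (17.1 ± 4.78 against 240.3 ± 85.1 TPM, -3.71 log2) and Ddit3 (15.3 ± 2.96 against 186 ± 68 TPM, -3.46 log2) fell. The tRNA synthetases fell as well (19 of 20 fell, adjusted p = 2.71e-11), as in Wars (-2.27 log2). Fibroblast markers (11 of 12 rose, 12 adjusted over the list alone, adjusted p = 2.12e-08), chemokines (12 of 18 rose and 1 fell, adjusted p = 0.000205) and mesothelium markers (5 of 5 rose, adjusted p = 0.00218) rose beside them. The TGF-β1 response list had a median of -0.24 but a camera direction of up (adjusted p = 0.961). In total 7633 genes passed, 3276 higher and 4357 lower, or 3886 and 3780 after centring. Interferon genes rose in 17 of 31 (adjusted p = 0.00724, estimated-correlation p = 0.6), a call that ended without Free_add_BCAA_TGFb replicate 1 (0.0502).

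Return of BCKA, which transaminases convert to BCAA, was tested in the same way. Cemip (2528 ± 80.5 against 70.7 ± 3.24 TPM, 5.14 log2, adjusted p = 8.34e-17), Acta1 (58.5 ± 5.31 against 0.8 ± 0.199 TPM, 5.05 log2, adjusted p = 4.26e-19) and the calcium channel Cacna1g (125 ± 9.21 against 3.16 ± 0.173 TPM, 4.92 log2, adjusted p = 6.93e-18) rose. The mitochondrial protein Chchd10 (2.5 ± 0.646 against 127 ± 54.3 TPM, -5.10 log2, adjusted p = 1.51e-13) and the actin-binding Avil (2.3 ± 0.606 against 110.5 ± 12.1 TPM, -5.09 log2, adjusted p = 1.87e-15) fell. Contractile genes (20 of 23 rose, 21 adjusted over the list alone, a median of 1.45 log2, adjusted p = 6.4e-13) rose, with Acta2 at 2291 ± 161 against 160.5 ± 48.6 TPM (log2 fold change 3.87). Matrix genes (24 of 41 rose and 2 fell, a median of 0.91 log2, adjusted p = 1.7e-08) rose, as in Fmod (4.18 log2). Col1a1 (16040 ± 2370 against 12740 ± 13000 TPM, adjusted p = 0.0662) and Col3a1 (5020 ± 233 against 7076 ± 5790 TPM, adjusted p = 0.592) did not pass. Without Free_TGFb replicate 1, Col1a1 passed (1.61 log2, adjusted p = 2.65e-10) and Col3a1 changed direction (0.435 log2, adjusted p = 0.00175). Without replicate 2, Col3a1 was lower (-0.614 log2, adjusted p = 0.0474). Sterol genes rose (23 of 27 rose, 24 adjusted over the list alone, adjusted p = 2.75e-17), as in Nsdhl (2.89 log2). Shortage genes fell (1 of 36 rose and 32 fell, adjusted p = 3.44e-12), as in Slc7a3 (-3.77 log2), as did tRNA synthetases (19 of 20 fell, adjusted p = 2.45e-11), as in Yars (-2.09 log2). Glycolysis genes rose (14 of 21 rose and 1 fell, 15 and 1 adjusted over the list alone, a median of 0.43 log2, adjusted p = 0.000552), led by Aldoc (4.33 log2). The TGF-β1 response list again differed in sign, with a median of -0.098 and a camera direction of up (adjusted p = 0.243). In total 7646 genes passed, 3280 higher and 4366 lower, or 3937 and 3725 after centring. Of the genes called with BCAA and with BCKA, 2970 rose in both (821.25 expected by chance) and 4026 fell in both (1453.9 expected), while 4 moved in opposite directions. Both comparisons share the Free_TGFb libraries, so data were simulated with unchanged groups and these shared libraries, which gave 0 shared calls. Top lists of the observed sizes, ranked by p in such simulations, shared 3955 genes of the same direction on average and 4032 at most. The observed calls shared 6996. Independent real effects were not simulated. Across genes, which are not independent replicates, the effect of removal and that of return had r = -0.985 for BCAA and -0.972 for BCKA. Shared libraries alone gave a simulated r of -0.499, and the covariances were -0.677 and -0.663 against a simulated -0.0152. Part of the excess can come from the shared Free_TGFb libraries, which were not split between the effects. Between removal under PBS and return under TGF-β1, which share none, r was -0.0236 for BCAA and -0.035 for BCKA.

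BCKA and BCAA differ in a keto group in place of the amino group, and both were compared directly under TGF-β1. Glycolysis genes were higher with BCKA: 6 of 21 rose, 16 adjusted over the list alone, with a median of 0.38 log2, adjusted p = 2.46e-45. These included the glucose transporter Slc2a1 (354 ± 36.2 against 224 ± 6.97 TPM, 0.66 log2, adjusted p = 0.00016) and the lactate exporter Slc16a3 (338 ± 6.32 against 208 ± 10.9 TPM, 0.70 log2, adjusted p = 1.41e-05). The pyruvate dehydrogenase kinase Pdk1 (105 ± 5.12 against 67.8 ± 2.1 TPM, 0.62 log2, adjusted p = 0.00011) was among them too. The oxygen-sensing hydroxylase Egln3 (102 ± 1.04 against 45.1 ± 2.11 TPM, 1.15 log2, adjusted p = 9.38e-06) and the semaphorin Sema7a (24 ± 3.66 against 9.34 ± 1.44 TPM, 1.27 log2, adjusted p = 0.00293) were higher as well. Of 13084 genes 35 passed, 29 higher and 6 lower, and 509 had an unadjusted p under 0.05 where chance gives 654.2. Among 28 genes of BCAA catabolism none passed under limma, but 9 were lower at an unadjusted p under 0.05 and the list had a median log2 fold change of -0.19 (adjusted p = 3.23e-10). No matrix gene passed under limma, and 4 of 41 were lower at an unadjusted p under 0.05. The matrix list had a median log2 fold change of -0.11 (adjusted p = 0.00264, estimated-correlation p = 0.289), a call that ended without Free_add_BCKA_TGFb replicate 1 (0.0657). The 95% interval of BCKA minus BCAA ran from -1.22 to 0.322 log2 for Col1a1, -0.323 to 0.342 for Acta2, -0.391 to 0.446 for Timp1 and -0.505 to 0.131 for Asns. It lay within 1 log2 of 0 for 13012 genes (99.4%) and within 0.5 log2 for 9357 (71.5%). The spread was pooled over all groups, Free_TGFb (Col1a1 at 4495 to 27680 TPM) included. Col1a1 was at 13660 to 18410 TPM with BCKA and 21040 to 22480 with BCAA, so its interval can be too wide. Without single libraries 16 to 26 genes passed.

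As a control for the medium itself, free medium with BCAA returned was compared with complete medium under TGF-β1. Lrg1, a secreted glycoprotein (2.55 ± 0.724 against 5.57 ± 0.673 TPM, log2 fold change -0.91, adjusted p = 0.0401), and haptoglobin, Hp (12.7 ± 0.203 against 23.4 ± 1.45 TPM, log2 fold change -0.83, adjusted p = 0.0401), were the 2 genes that passed. An unadjusted p under 0.05 was found for 262 genes, where chance gives 654.2. Acta2 stood at 2278 ± 194 against 2358 ± 475 TPM, Col1a1 at 21710 ± 724 against 23480 ± 1570 TPM and Asns at 126 ± 14.8 against 128 ± 24.9 TPM. No list call held with an estimated correlation. Ribosomal protein genes, for example, had a median log2 fold change of -0.16 (adjusted p = 1.15e-11, estimated-correlation p = 0.281) and nuclear oxidative phosphorylation genes -0.14 (adjusted p = 1.53e-09, estimated-correlation p = 0.276). Both were above 0 without Complete_TGFb replicate 2 (0.0292 and 0.0272). Endoplasmic reticulum folding genes had one of -0.072 (adjusted p = 0.00341, estimated-correlation p = 0.217), a call that ended without the same library (0.17). Without any 1 of the 6 libraries no gene passed under limma, except 1 without Free_add_BCAA_TGFb replicate 3.

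**Figure D1:**
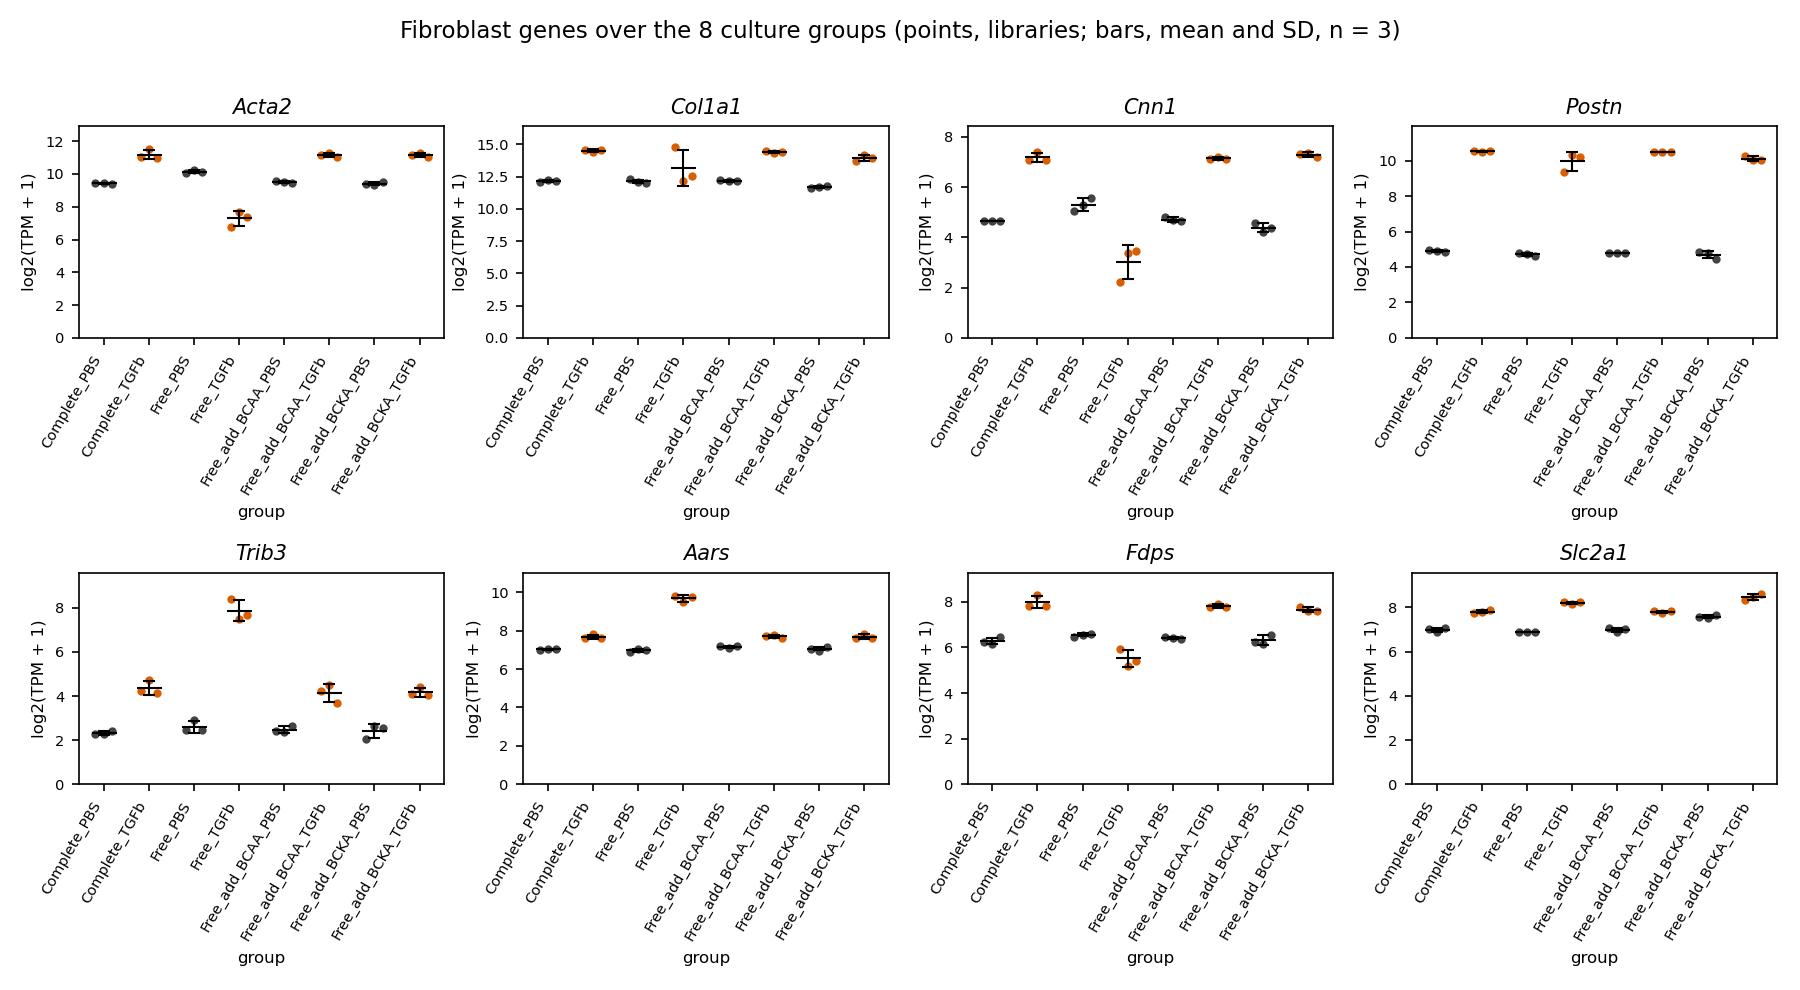
Level of 8 genes in each fibroblast group, as log2(TPM + 1), with a dot per library and bars for mean and SD (n = 3). Acta2 was low in TGF-β1 treated cells in free medium (160.5 ± 48.6 against 2358 ± 475 TPM for free against complete medium) and returned with either BCAA or BCKA.

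In the water experiment, bleomycin lungs were first compared with PBS lungs on day 14. The macrophage elastase Mmp12 (126 ± 75.1 against 1.34 ± 0.373 TPM, 5.63 log2, adjusted p = 4.43e-05) rose most. Tenascin C, Tnc (103 ± 9.68 against 4.17 ± 0.722 TPM, 4.34 log2, adjusted p = 7.12e-07), and fibronectin, Fn1 (363 ± 131 against 21.4 ± 3.65 TPM, 3.96 log2, adjusted p = 8.58e-06), rose too. Falls were largest for haem oxygenase 1, Hmox1 (182 ± 54.9 against 4381 ± 624 TPM, -4.62 log2, adjusted p = 4.47e-06). The cystine transporter Slc7a11 (2.87 ± 1.69 against 74.2 ± 7.21 TPM, -4.37 log2, adjusted p = 8.3e-06) and the heat shock protein Hspa1b (17.3 ± 4.42 against 284 ± 20.5 TPM, -3.99 log2, adjusted p = 4.47e-06) fell too. Of the matrix genes, 35 of 41 rose, 36 adjusted over the list alone, with a median of 1.73 log2, adjusted p = 2.32e-23, estimated-correlation p = 0.268. Col1a1 (364 ± 64.6 against 54.5 ± 14.8 TPM, 2.73 log2), Col3a1 (424 ± 93.7 against 80.4 ± 25.3 TPM, 2.41 log2) and the protease inhibitor Timp1 (2.55 log2) rose. Monocyte-derived macrophage markers rose (15 of 16 rose, a median of 2.60 log2, adjusted p = 2.28e-14, estimated-correlation p = 0.168). They included osteopontin, Spp1 (3337 ± 306 against 335 ± 94 TPM, 3.34 log2), Gpnmb (3.82 log2) and arginase 1, Arg1 (20.3 ± 10.3 against 0.923 ± 0.379 TPM, 3.39 log2). Cell division genes rose (32 of 37 rose, 35 adjusted over the list alone, adjusted p = 3.5e-16, estimated-correlation p = 0.392), as in Cdk1 (11.3 ± 2.86 against 1.68 ± 0.599 TPM, 2.20 log2). TGF-β1 response genes rose as well (19 of 29 rose, 21 adjusted over the list alone, adjusted p = 7.99e-07, estimated-correlation p = 0.392). The secreted antagonist Grem1 (11.5 ± 3.56 against 0.369 ± 0.0607 TPM, 3.16 log2) and Ccn2 (348 ± 159 against 105 ± 23.5 TPM, 1.65 log2) were among them. The amino acid shortage response fell (28 of 35 fell, 29 adjusted over the list alone, a median of -1.20 log2, adjusted p = 6.01e-26, estimated-correlation p = 0.0698). From high levels in the PBS lungs, Asns (33.6 ± 4.02 against 102 ± 11.7 TPM, -1.57 log2), Chac1 (-3.57 log2) and Slc7a5 (-2.80 log2) fell. Club cell markers (5 of 7 fell, 7 adjusted over the list alone, adjusted p = 4.71e-06, estimated-correlation p = 0.0698), such as Cyp2f2 (-1.59 log2), and cardiac markers (5 of 7 fell, 6 adjusted over the list alone, adjusted p = 0.000257, estimated-correlation p = 0.421) fell beside these groups. Neutrophil markers fell too (1 of 9 fell, 6 adjusted over the list alone, adjusted p = 0.00236, estimated-correlation p = 0.537). Alveolar type 1 markers (6 of 10 rose, 7 rose and 1 fell adjusted over the list alone, adjusted p = 0.0262, estimated-correlation p = 0.564) rose, as in Pdpn (1.41 log2), a call that ended without BLM_NW replicate 3 (0.0825). Acta2 did not pass (391 ± 161 against 318 ± 46.1 TPM, adjusted p = 0.599). In total 3773 of 17209 genes passed, 2555 higher and 1218 lower, and 2462 and 2116 after centring.

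Whether BCAA in drinking water changed the bleomycin lung was asked next. Matrix genes were higher: 14 of 41 rose, 23 adjusted over the list alone, with a median of 0.62 log2, adjusted p = 1.59e-15, estimated-correlation p = 0.278. Type VII collagen, Col7a1 (18.4 ± 2.67 against 4.49 ± 1.37 TPM, 1.84 log2, adjusted p = 0.0079), type V collagen, Col5a3 (34 ± 3.51 against 9.83 ± 1.97 TPM, 1.71 log2, adjusted p = 0.00787), and fibulin 2, Fbln2 (51.7 ± 7.62 against 17.2 ± 4.43 TPM, 1.55 log2, adjusted p = 0.0103), rose. So did Col1a1 (932 ± 223 against 364 ± 64.6 TPM, 1.34 log2) and Fn1 (838 ± 135 against 363 ± 131 TPM, 1.26 log2). Col3a1 (597 ± 58.7 against 424 ± 93.7 TPM, adjusted p = 0.32), Timp1 (855 to 1064 against 287 to 358 TPM, adjusted p = 0.133) and Acta2 (adjusted p = 0.408) did not pass. The Timp1 spread was pooled with PBS_NW lungs (31.65 to 146.1 TPM). The neutrophil surface protein Cd177 (218 ± 41 against 55.2 ± 31.7 TPM, 2.17 log2, adjusted p = 0.036) and Rasd1 (2.02 log2) rose most. The cartilage protein Chad (3 ± 0.258 against 12.2 ± 2.52 TPM, -1.71 log2, adjusted p = 0.00787), paraoxonase Pon1 (7.52 ± 1.52 against 26 ± 3.88 TPM, -1.67 log2, adjusted p = 0.00787) and the GABA receptor subunit Gabrp (-1.65 log2) fell most. Macrophage markers rose in part (2 of 16 rose, 11 rose and 1 fell adjusted over the list alone, a median of 0.75 log2, adjusted p = 6.29e-08, estimated-correlation p = 0.278). Those that passed were Arg1 (78.3 ± 26.9 against 20.3 ± 10.3 TPM, 1.94 log2) and Spp1 (8631 ± 900 against 3337 ± 306 TPM, 1.37 log2). Alveolar macrophage markers (1 of 10 rose, 6 adjusted over the list alone, adjusted p = 0.000102, estimated-correlation p = 0.278) included Chil3 (1.73 log2). TGF-β1 response genes (4 of 29 rose, 9 adjusted over the list alone, adjusted p = 7.23e-06, estimated-correlation p = 0.278) included Grem1 (40.9 ± 4.63 against 11.5 ± 3.56 TPM, 1.77 log2). Glycolysis genes (4 of 21 rose, 12 adjusted over the list alone, adjusted p = 2.42e-10, estimated-correlation p = 0.278) included Eno1 (0.78 log2) and Pkm (0.65 log2). Alveolar type 2 markers were lower in part (2 of 10 fell, 5 adjusted over the list alone, a median of -0.59 log2, adjusted p = 1.54e-08, estimated-correlation p = 0.278). Those that passed were Slc34a2 (-0.94 log2) and Sftpa1 (928 ± 61 against 1651 ± 122 TPM, -0.83 log2). Club cell markers (2 of 7 fell, 4 adjusted over the list alone, adjusted p = 2.38e-05, estimated-correlation p = 0.163), such as Aldh1a7 (-1.01 log2), were also lower. So were red blood cell markers (2 of 5 fell, 4 adjusted over the list alone, adjusted p = 1.61e-07, estimated-correlation p = 0.163). Asns stood at 32.1 ± 6.17 against 33.6 ± 4.02 TPM (adjusted p = 0.862). Ribosomal protein genes showed no member past the threshold over all genes but 59 of 75 rose adjusted over the list alone (a median of 0.58 log2, adjusted p = 1.75e-21, estimated-correlation p = 0.327). In total 207 genes passed, 150 higher and 57 lower, or 214 and 134 after centring. The count depended on each library, 14 to 591 without single ones. Of the 19 genes named as changed, 5 and 13 lost their call without BLM_NW replicates 1 and 3 (adjusted p up to 0.089 and 0.154), and 8, 9 and 10 without BLM_BCAA replicates 1, 2 and 3 (up to 0.102, 0.14 and 0.144). Col7a1, Col5a3, Fbln2, Chad, Pon1 and Grem1 passed without any single library.

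In the diet experiment, bleomycin lungs were compared with PBS lungs on day 21. Osteopontin, Spp1 (9267 ± 3550 against 19.9 ± 7.82 TPM, 8.82 log2, adjusted p = 3.55e-09), fibronectin, Fn1 (1135 ± 71.5 against 11.6 ± 2.48 TPM, 6.52 log2, adjusted p = 2.8e-10), and the acute phase protein Saa3 (363 ± 267 against 2.68 ± 1.33 TPM, 6.42 log2, adjusted p = 2.55e-07) rose most. The trefoil peptide Tff2 (3.44 ± 2.26 against 268 ± 43.6 TPM, -6.04 log2, adjusted p = 2.52e-08), the glutathione transferase Gsta1 (3.61 ± 3.62 against 251 ± 103 TPM, -5.91 log2, adjusted p = 1.7e-05) and the acyl-CoA synthetase Acsm1 (1.46 ± 0.215 against 122 ± 10.8 TPM, -5.65 log2, adjusted p = 1.25e-09) fell most. Of the matrix genes, 39 of 41 rose, with a median of 3.41 log2, adjusted p = 8.04e-15, estimated-correlation p = 0.134. Both Col1a1 (1328 ± 280 against 90.8 ± 18.7 TPM, 3.85 log2) and Col3a1 (742 ± 29.3 against 71.4 ± 12.4 TPM, 3.37 log2) rose. Rises were also seen in macrophage markers (16 of 16 rose, adjusted p = 4.99e-06, estimated-correlation p = 0.253) and TGF-β1 response genes (29 of 29 rose, adjusted p = 2.45e-08, estimated-correlation p = 0.171), such as Ccn4 (3.94 log2). Targets of p53 rose (20 of 23 rose, adjusted p = 0.000472, estimated-correlation p = 0.323), such as Cdkn1a (2.57 log2). Markers of other cells moved with them, but the PBS_ND lungs stood apart from the PBS lungs of the other experiments. Their mean log2 level of ciliated minus alveolar type 1 and endothelial markers was 2.77 to 3.34, against -1.64 to -0.573 in the other PBS lungs. Changes in this comparison can thus come from the PBS_ND samples as well as from bleomycin. Endothelium markers rose (12 of 14 rose, adjusted p = 2.32e-05, estimated-correlation p = 0.221), such as Cdh5 (4.22 log2). So did alveolar type 1 markers (9 of 10 rose, adjusted p = 0.00107, estimated-correlation p = 0.353), such as Ager (3.39 log2). Club cell markers fell (6 of 7 fell, 7 adjusted over the list alone, adjusted p = 2.45e-08, estimated-correlation p = 0.12), such as Scgb3a2 (-4.08 log2). So did ciliated cell markers (10 of 10 fell, adjusted p = 6.51e-12, estimated-correlation p = 0.134) and cardiac markers (9 of 9 fell, adjusted p = 1.74e-09, estimated-correlation p = 0.198), such as Myh6 (-4.70 log2). Acta2 did not pass (554 ± 78.7 against 601 ± 132 TPM, adjusted p = 0.668). In total 11328 of 18593 genes passed, 9047 higher and 2281 lower. Centring moved the median of all genes by 0.564 log2, and relative to it 4515 were higher and 4696 lower, with a median of 2.85 for matrix genes.

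Whether a BCAA-free diet, begun on day 7, changed the bleomycin lung was the question of the next comparison. Matrix genes were lower: 1 of 41 rose and 31 fell, 2 and 34 adjusted over the list alone, with a median of -1.13 log2, adjusted p = 4.77e-22, estimated-correlation p = 0.102. The protease inhibitor Timp1 (151 ± 43.7 against 1386 ± 464 TPM, -3.18 log2, adjusted p = 6.82e-05), tenascin C, Tnc (38.9 ± 12.1 against 219 ± 60.9 TPM, -2.47 log2, adjusted p = 0.000178), and type V collagen, Col5a3 (7.12 ± 3.45 against 52.2 ± 18 TPM, -2.76 log2, adjusted p = 0.000657), fell. Col1a1 (408 ± 54.5 against 1328 ± 280 TPM, -1.69 log2, adjusted p = 0.000247), Fn1 (395 ± 61.1 against 1135 ± 71.5 TPM, -1.53 log2, adjusted p = 0.000203) and Cthrc1 (11.6 ± 3.95 against 67.1 ± 12.1 TPM, -2.47 log2) fell too. The largest falls were in Saa3 (15.4 ± 6.87 against 363 ± 267 TPM, -4.28 log2, adjusted p = 0.000268) and the cytokine Tnfsf18 (-3.63 log2). Cell division genes fell (26 of 37 fell, 32 adjusted over the list alone, a median of -1.16 log2, adjusted p = 4.77e-22, estimated-correlation p = 0.102). Both Cdk1 (2.91 ± 0.956 against 15.1 ± 1.79 TPM, -2.06 log2) and Ccnb2 (-2.12 log2) fell. Macrophage markers fell (8 of 16 fell, adjusted p = 0.000316, estimated-correlation p = 0.292), as in Arg1 (12.6 ± 4.56 against 106 ± 57.3 TPM, -2.82 log2) and Spp1 (2322 ± 584 against 9267 ± 3550 TPM, -1.95 log2). TGF-β1 response genes fell (12 of 29 fell, 1 rose and 18 fell adjusted over the list alone, adjusted p = 1.84e-08, estimated-correlation p = 0.11), as in Ccn4 (-2.30 log2) and Inhba (-2.39 log2). Of the chemokines, 1 of 32 rose and 10 fell, 2 and 15 adjusted over the list alone (adjusted p = 0.000332, estimated-correlation p = 0.234), as in Ccl2 (-2.87 log2), whereas Il33 (1.89 log2) rose. Alveolar type 2 markers were higher (9 of 10 rose, 10 adjusted over the list alone, a median of 1.04 log2, adjusted p = 9.21e-12, estimated-correlation p = 0.102), as in Sftpa1 (3375 ± 677 against 816 ± 128 TPM, 2.04 log2) and Lamp3 (1.67 log2). Fibroblast markers were higher (6 of 13 rose and 1 fell, 7 and 1 adjusted over the list alone, adjusted p = 2.52e-06, estimated-correlation p = 0.132), as in Inmt (1687 ± 165 against 355 ± 107 TPM, 2.29 log2) and Gsn (1.55 log2). Club cell markers were higher too (3 of 7 rose, 4 adjusted over the list alone, adjusted p = 7.96e-06, estimated-correlation p = 0.102). The muscle genes Tcap (45.1 ± 19 against 4.25 ± 2.93 TPM, 3.30 log2, adjusted p = 0.00431) and Myh6 (3.19 log2) rose, as did Hspa1b (371 ± 88.2 against 42.7 ± 28.2 TPM, 3.24 log2, adjusted p = 0.000909). Cardiac markers (5 of 9 rose, 6 adjusted over the list alone, adjusted p = 2.34e-07, estimated-correlation p = 0.234) and adipocyte markers (4 of 5 rose, adjusted p = 0.000196, estimated-correlation p = 0.234) rose beside these groups. Of 35 shortage genes 4 rose (camera adjusted p = 0.153), and Asns stood at 37.8 ± 3.13 against 33.1 ± 3.6 TPM (adjusted p = 0.657). In total 1885 genes passed, 748 higher and 1137 lower. Centring moved the median by -0.127 log2, and 1380 were then higher and 1095 lower. BLM_BCAA_free replicate 3 listed 17554 genes above 0 and 16.5% mitochondrial TPM. Without it 32 of 41 matrix genes and 28 of 37 cell division genes fell, and 9 of 10 type 2 markers and 8 of 35 shortage genes rose. The count was 908 and 989 without BLM_ND replicates 1 and 3.

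In the BT2 experiment, with the higher bleomycin dose, DMSO-treated bleomycin lungs were compared with PBS lungs. Arginase 1, Arg1 (472 ± 290 against 1.72 ± 0.613 TPM, 7.30 log2, adjusted p = 4.69e-05), Tnc (263 ± 117 against 3.35 ± 1.11 TPM, 5.83 log2, adjusted p = 0.00018), Timp1 (1546 ± 577 against 26.1 ± 4.16 TPM, 5.76 log2, adjusted p = 6.52e-05) and Spp1 (13550 ± 4570 against 294 ± 146 TPM, 5.59 log2, adjusted p = 6.77e-05) rose most. Falls were largest for Hspa1b (20.2 ± 7.88 against 800.2 ± 193 TPM, -5.28 log2, adjusted p = 8.55e-05) and myoglobin, Mb (0.778 ± 0.378 against 73.3 ± 39.8 TPM, -5.21 log2, adjusted p = 7.66e-05). Of the matrix genes, 34 of 41 rose, 36 adjusted over the list alone, with a median of 2.25 log2, adjusted p = 1.57e-17, estimated-correlation p = 0.348. Fn1 (1289 ± 298 against 35.4 ± 3.23 TPM, 5.13 log2), Col1a1 (1116 ± 165 against 62.1 ± 15.9 TPM, 4.17 log2) and Col3a1 (799 ± 85.6 against 48.7 ± 8.76 TPM, 4.02 log2) rose. The stromelysin Mmp10 stood at 19.6 ± 3.04 TPM and is listed at 0 in all PBS lungs. Macrophage markers rose (14 of 16 rose, adjusted p = 3.73e-14, estimated-correlation p = 0.306), as in Trem2 (5.40 log2). Chemokines rose (16 of 32 rose and 1 fell, 20 and 1 adjusted over the list alone, adjusted p = 4.65e-08, estimated-correlation p = 0.306), as in Ccl2 (4.77 log2). Cell division genes (30 of 37 rose, 32 adjusted over the list alone, adjusted p = 1.07e-14, estimated-correlation p = 0.443) and ribosomal protein genes (66 of 75 rose, 71 rose and 1 fell adjusted over the list alone, adjusted p = 3.81e-16, estimated-correlation p = 0.598) rose as well. Amino acid shortage genes fell (23 of 35 fell, 27 adjusted over the list alone, a median of -1.38 log2, adjusted p = 3.05e-11, estimated-correlation p = 0.306). Asns (36 ± 6.5 against 107 ± 11.6 TPM, -1.56 log2) fell. For this list the diet experiment gave positive medians (0.124 and 0.163 without PBS_ND replicates 1 and 3). Falls here and in the water experiment can reflect PBS lungs too. Alveolar type 2 markers (6 of 10 fell, 9 adjusted over the list alone, adjusted p = 0.000341, estimated-correlation p = 0.623), such as Sftpc (7060 ± 5290 against 48430 ± 6640 TPM, -3.21 log2), fell beside these groups. Cardiac markers fell too (8 of 8 fell, adjusted p = 1.43e-07, estimated-correlation p = 0.348), such as Myh6 (-4.23 log2). In total 5550 of 18151 genes passed, 3132 higher and 2418 lower, or 3368 and 3190 after centring. The count was 3334 to 7099 without single libraries.

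BT2-treated bleomycin lungs were then compared with DMSO-treated ones. Macrophage genes were lower, with Arg1 (8.45 ± 4.75 against 472 ± 290 TPM, -5.60 log2, adjusted p = 0.00172) and the complement receptor Vsig4 (0.34 ± 0.232 against 25.9 ± 10.2 TPM, -4.28 log2, adjusted p = 0.000769) falling most. Of the macrophage markers 11 of 16 fell (a median of -1.50 log2, adjusted p = 1.53e-08, estimated-correlation p = 0.552), as in Spp1 (1555 ± 621 against 13550 ± 4570 TPM, -3.13 log2) and Mrc1 (-2.23 log2). Of the matrix genes, 18 of 41 fell, 1 rose and 24 fell adjusted over the list alone, with a median of -1.02 log2, adjusted p = 3.94e-12, estimated-correlation p = 0.552. Fbln2 (-2.94 log2), Thbs1 (111 ± 67.9 against 713 ± 413 TPM, -2.65 log2) and Tnc (-2.80 log2) fell. Further falls were those of Timp1 (162 ± 110 against 1546 ± 577 TPM, -3.36 log2, adjusted p = 0.00553), the crosslinking enzyme Lox (-2.55 log2), Ccl2 (-2.93 log2) and the growth factor Ereg (-3.50 log2). TGF-β1 response genes fell (8 of 29 fell, 14 adjusted over the list alone, adjusted p = 5.28e-08, estimated-correlation p = 0.552), as in Inhba (-2.53 log2) and Ccn4 (-2.70 log2). Acta2 (292 ± 91.3 against 753 ± 104 TPM, -1.40 log2), Col1a1 (410.2 ± 261 against 1116 ± 165 TPM, -1.63 log2) and Fn1 (412 ± 289 against 1289 ± 298 TPM, -1.84 log2) were lower too. Ccn2 (285 ± 117 against 696 ± 404 TPM, adjusted p = 0.0612) did not pass, but did without BLM_DMSO replicate 3 (0.0293) or BLM_BT2 replicate 2 (0.0453). Complement C5, Hc (169.9 ± 55.3 against 9.14 ± 9.01 TPM, 4.51 log2, adjusted p = 0.00704), rose most. The chitinase-like Chil1 (965 ± 145 against 63.1 ± 53 TPM, 4.30 log2, adjusted p = 0.00508) and the amino acid transporter Slc7a10 (29.8 ± 17.6 against 0.747 ± 0.471 TPM, 3.99 log2, adjusted p = 0.00306) followed. All alveolar type 2 markers rose (10 of 10 rose, a median of 2.12 log2, adjusted p = 3.74e-07, estimated-correlation p = 0.552), as in Sftpc (51540 ± 14700 against 7060 ± 5290 TPM, 3.27 log2) and Slc34a2 (3.02 log2). Club cell (3 of 7 rose, adjusted p = 0.0111, estimated-correlation p = 0.63) and cardiac markers (3 of 8 rose, 6 adjusted over the list alone, adjusted p = 0.00434, estimated-correlation p = 0.6) rose beside them. B and plasma cell (3 of 13 rose, 7 adjusted over the list alone, adjusted p = 0.000715, estimated-correlation p = 0.589) and T cell markers (2 of 12 rose, 6 adjusted over the list alone, adjusted p = 0.0016, estimated-correlation p = 0.632) did as well. Ribosomal protein genes fell (24 of 75 fell, 70 adjusted over the list alone, adjusted p = 1.43e-23, estimated-correlation p = 0.552). Without BLM_DMSO replicate 1, with the lowest type 2 marker levels, 1 of 75 fell, as did 11 of 41 matrix genes and 7 of 16 macrophage markers, while 10 of 10 type 2 markers, 0 of 13 B and plasma cell and 0 of 12 T cell markers rose. BLM_DMSO replicate 3 stood apart in another way, with a mean log2 level of ciliated minus alveolar type 1 and endothelial markers of 0.525, against -2.63 and -2.81 in replicates 1 and 2. In total 2133 genes passed, 1151 higher and 982 lower. Centring moved the median by 0.11 log2, and 1652 were then higher and 1663 lower. The count was 138 to 4989 without single libraries. Without BLM_DMSO replicate 2 the calls of club cell (0.272), T cell (0.0653), B cell (0.0608) and cardiac markers (0.0846) ended. Of the 21 genes named as changed, 5 and 1 lost their call without BLM_DMSO replicates 1 and 3 (adjusted p up to 0.0646 and 0.0517), and 7, 1 and 8 without BLM_BT2 replicates 1, 2 and 3 (up to 0.0875, 0.0542 and 0.116). All were among Acta2, Col1a1, Fn1, Thbs1, Tnc, Inhba, Sftpc and Slc34a2.

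Each treatment was tested on genes that bleomycin changed in both other experiments, so that no library was shared. PBS lungs differed between experiments, so the sets can reflect them as well as bleomycin. In the water experiment, 1140 genes that rose with bleomycin elsewhere had a median of 0.52 log2 with BCAA (101 rose and 0 fell, camera adjusted p = 2.85e-42, adjusted p = 0.0314 with an estimated correlation). The 456 that fell had -0.37 (26 fell and 1 rose, 6.78e-29 and 0.0209). With the BCAA-free diet, 600 genes of the first kind had a median of -0.91 (347 fell and 1 rose, 1.37e-52 and 0.0124) and 325 of the second 0.66 (104 rose, 3.54e-33 and 0.043). With BT2 the medians were -0.43 for 699 genes (154 fell and 20 rose, 5.17e-16) and 1.08 for 161 genes (56 rose and 1 fell, 1.53e-17). These calls were lost with an estimated correlation (adjusted p = 0.223 and 0.166). Within an experiment, across genes, which are not independent replicates, the bleomycin effect and the treatment effect had r = 0.0378 for water, -0.455 for diet and -0.786 for BT2. Both effects share the bleomycin libraries, which alone gave simulated values of -0.5, -0.498 and -0.501. Covariances were 0.00977, -0.288 and -0.491 against simulated -0.0419, -0.0517 and -0.0618. With the 4 BLM_ND libraries split between the effects, r was -0.417 to -0.343 in the diet experiment. The bleomycin libraries of the other experiments were not split, so part of the BT2 excess can come from sharing.

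**Figure D2:**
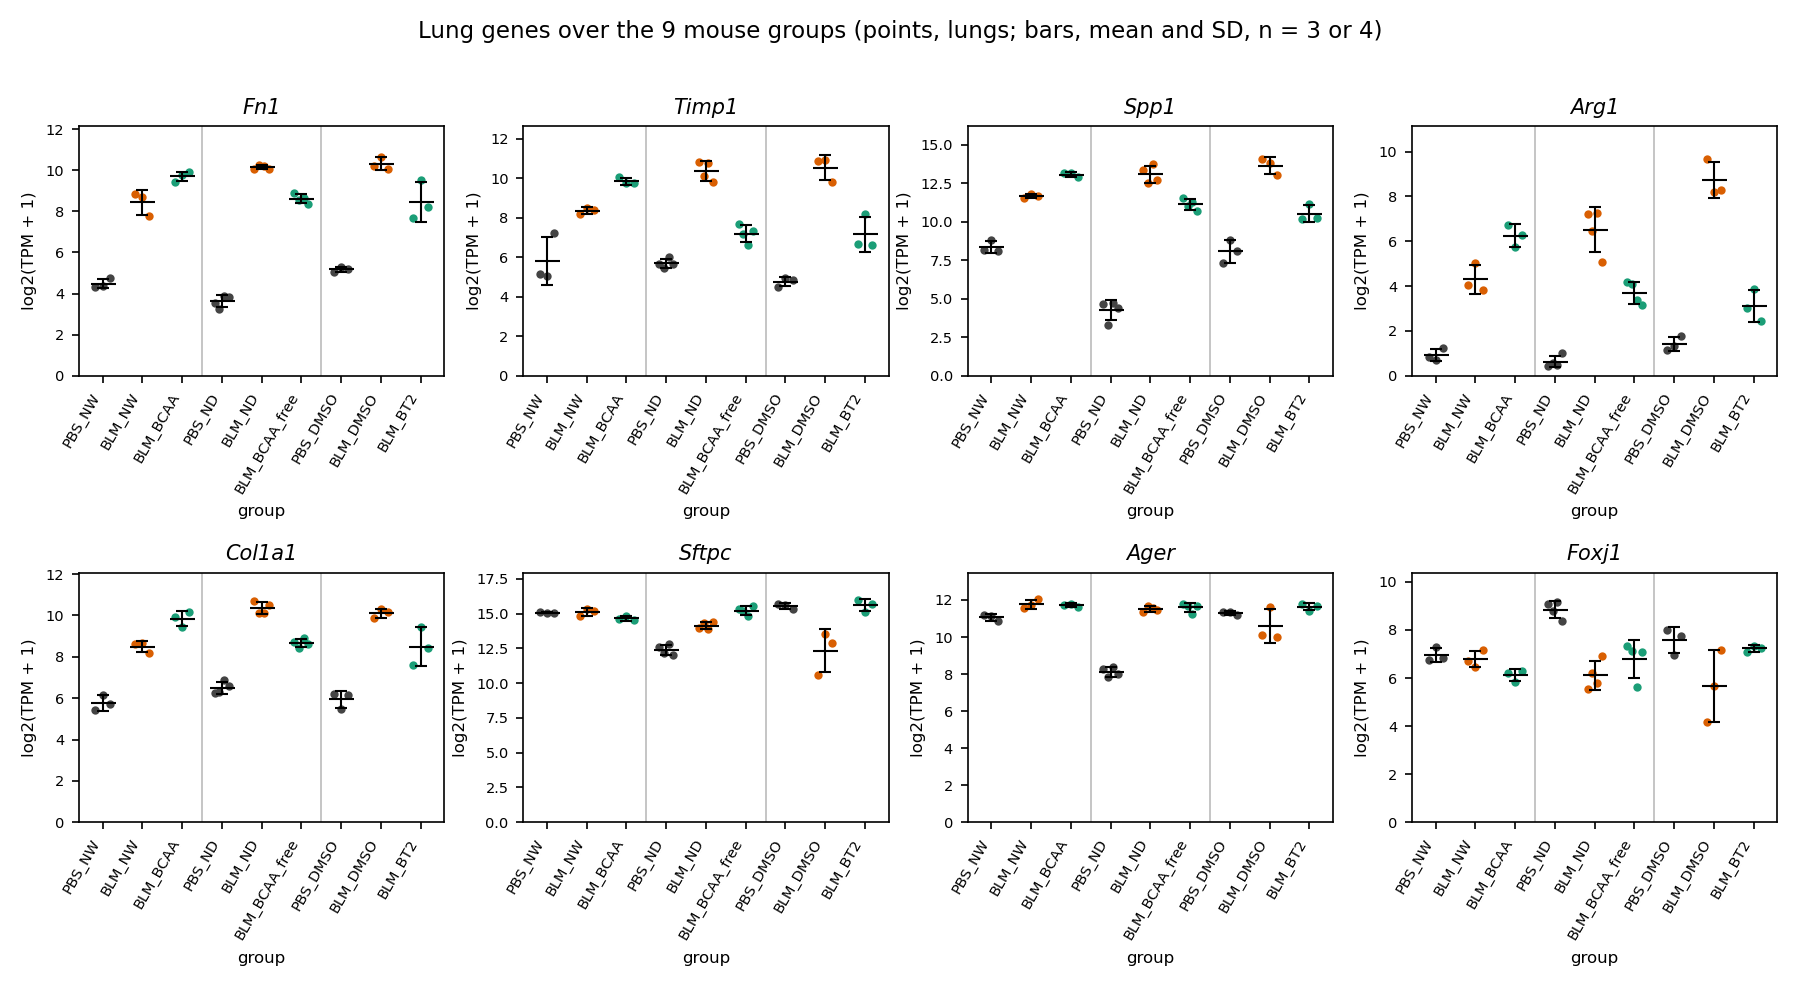
Level of 8 genes in each lung group, as log2(TPM + 1), with a dot per library and bars for mean and SD (n = 3, or n = 4 in the diet experiment). Timp1 fell with the BCAA-free diet (151 ± 43.7 against 1386 ± 464 TPM) and with BT2 (162 ± 110 against 1546 ± 577 TPM).

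**Figure D3:**
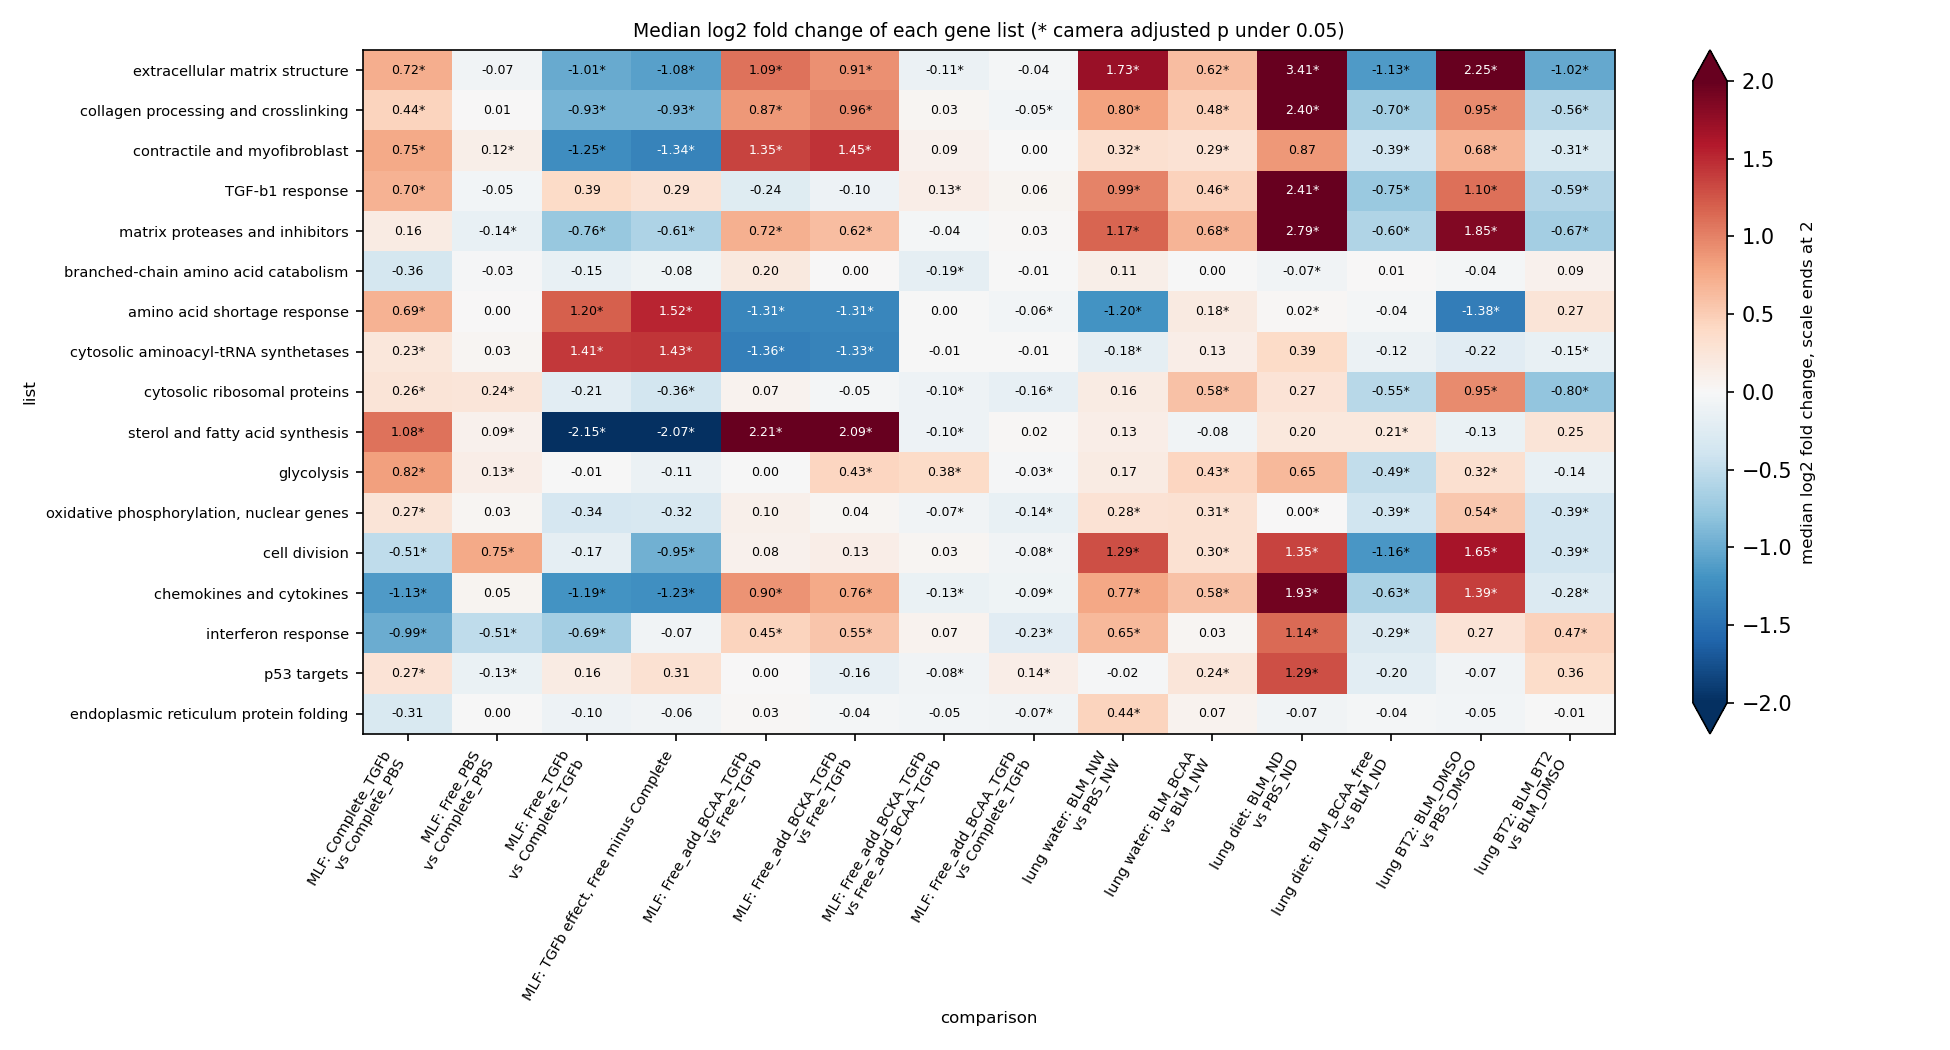
Median log2 fold change of the 17 gene lists in the 14 comparisons, with a star where camera adjusted p was under 0.05 and a colour scale that ends at 2. Matrix genes had medians of 0.62 with BCAA in water, -1.13 with the BCAA-free diet and -1.02 with BT2, calls that were lost with an estimated correlation (adjusted p = 0.278, 0.102 and 0.552).

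**Figure D4:**
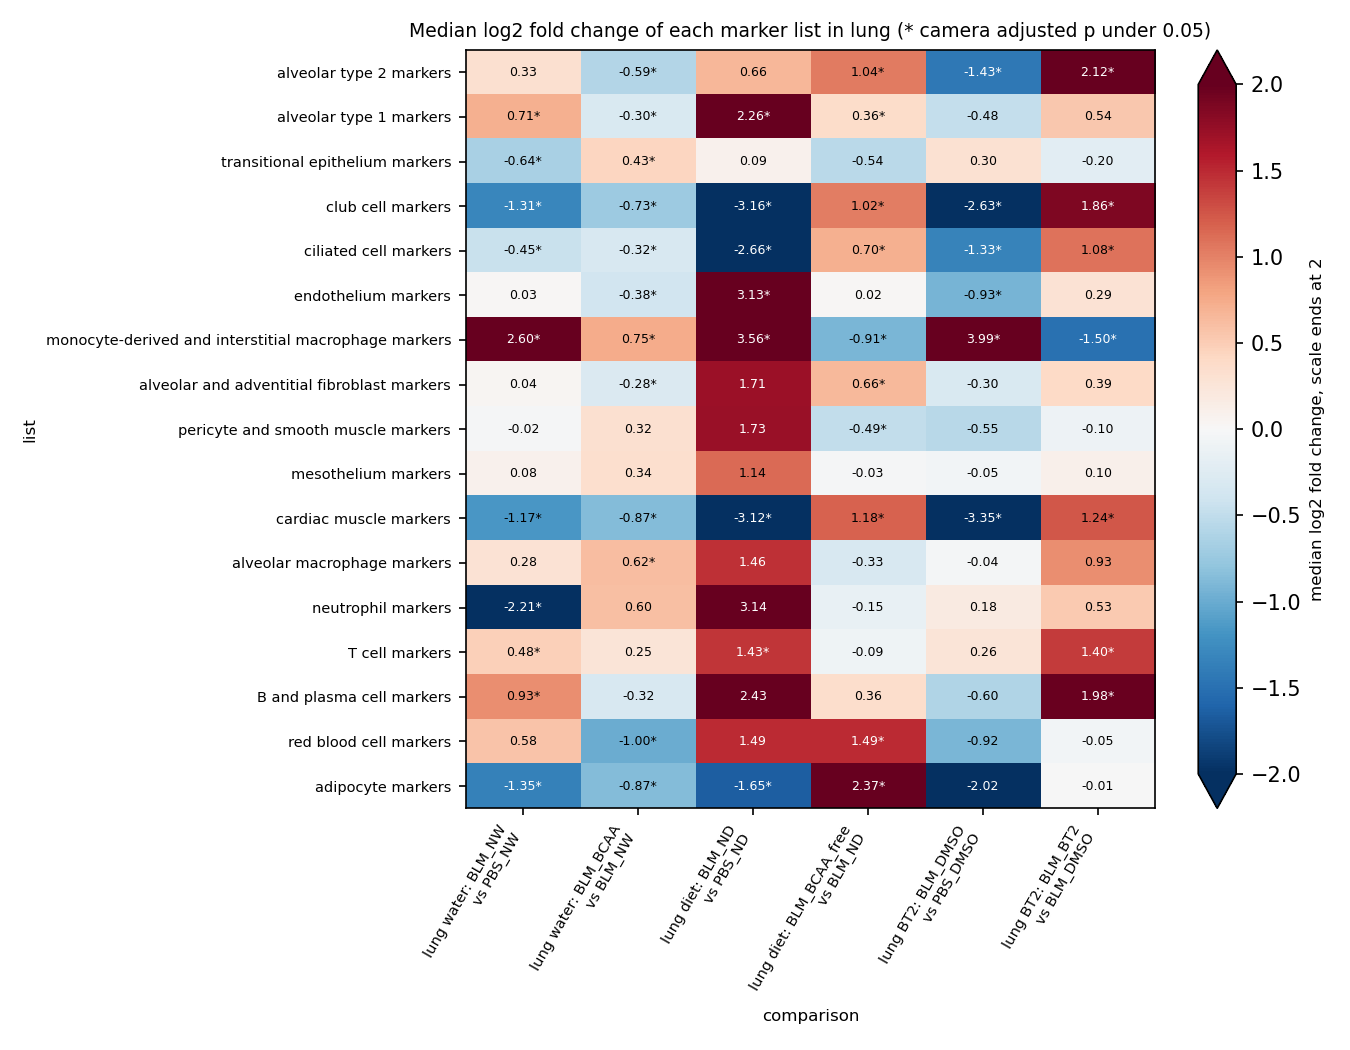
Median log2 fold change of the 17 cell type marker lists in the 6 lung comparisons, on the same scale and with the same star. Alveolar type 2 markers had medians of -0.59, 1.04 and 2.12 with the same treatments (adjusted p = 0.278, 0.102 and 0.552 with an estimated correlation).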

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

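Of the tests below, the GC content test of the fibroblast library, the tests of TPM shares and of another part of the lung, and the test of depth were chosen only after the results were seen.

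The difference between the responses to TGF-β1 with and without BCAA passed limma for 6 of the 11 fixed genes reported. On the log2 scale it was -1.31 for Col1a1, -4.6 for Acta2, -1.99 for Timp1, -0.688 for Ppm1k, 0.955 for Bcat1 and 0.571 for Asns. The call of Col1a1 was lost without any of the compared libraries but Free_TGFb replicate 1 (adjusted p from 0.0534 to 0.141). Among the 4 lungs with the BCAA-free diet, replicate 4 had the highest Bcat1, 0.278 TPM against 0.209 ± 0.00303 in the others, a gap of 0.92 of the group's range. Replicate 3 had the lowest Bcat2, 15.7 against 38.5 ± 1.3 TPM (a gap of 0.892 of the range), the fewest genes above 0, 17554 (0.839), and the highest mitochondrial share, 16.5 against 4.87 ± 0.691% (0.894). A gap above Dixon's critical value was found in 4 of 48 ratios computed, and chance gives about 1 in 20.

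Free_TGFb replicate 1 stood apart from replicates 2 and 3, with an SD of the difference across genes of 0.643 log2, against 0.246 between replicates 2 and 3 and at most 0.377 in another fibroblast group. Bias by GC content or length is argued against, since 0.614 remained after its trend was removed, a ratio of 0.954. A mixed or part-rescued culture would move genes of both directions alike towards complete medium, but the median share of that way was 0.221 for genes that rose without BCAA and -0.0325 for those that fell, a difference of -0.254. A wrong label is argued against by a correlation of 0.961 with its own group and at most 0.904 with another, a difference of -0.0569. What set it apart stays open, and no biological explanation was tested.

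In the diet experiment, alveolar type 1 and endothelium markers were low in PBS_ND lungs and higher after bleomycin, 21 of 24 of them called, with a median of 2.83 log2. TPM shares taken by a few abundant genes are argued against as the whole cause: after centring 21 of 24 were called, with a median of 2.26. The same holds for GC content and length, with 21 of 24 called and a median of 2.24. The difference of ciliated minus alveolar and endothelial markers was 2.77 to 3.34 in PBS_ND lungs and -1.64 to -0.573 in the other 6 PBS lungs, a gap of 3.34 between the nearest, so PBS_ND samples may hold more airway. An effect of diet or day on healthy lungs stays open, since every PBS_ND lung shares both.

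BLM_BCAA_free replicate 3 listed few low genes and much mitochondrial RNA. Lower depth or few distinct RNA molecules stay open, because depth is unknown and the mitochondrial share, 2.92 times the highest of the other libraries of its group, is part of the pattern and so no test of them. Bias by GC content or length is argued against as the whole cause: the correlation with its group rose from 0.844 to 0.89 when the trend was removed, and other libraries of the group had at least 0.978 before. A wrong label is argued against by a correlation of at most 0.82 with another group, a difference of -0.0244. Damage to the tissue or RNA stays open, and no biological explanation was tested.

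For 3 against 3 libraries, 10 splits are too few for a share under 0.05, and each time only the real one gave a count as large. In fibroblasts the real counts and the highest of the other splits were 6357 and 0 for TGF-β1, 119 and 0 for removal of BCAA, 7895 and 1493 for removal under TGF-β1, 7633 and 140 for return of BCAA, 7646 and 1000 for return of BCKA, 35 and 0 for BCKA against BCAA, and 2 and 0 for BCAA returned against complete medium. In lungs the highest other count was 1 in the water and BT2 experiments. For the difference of responses, 2 of 100 drawn splits were as large, the real one with 6225 and another with 6243. The TGF-β1 libraries set this count, since the 7 draws that kept them as labelled gave at least 5699 and the highest with them mixed was 37, and their 10 splits are too few as well. For bleomycin in the diet experiment (11328, highest other 1) and the BCAA-free diet (1885, highest other 93), 1 of 35 splits was as large, so chance can be excluded.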

How the results depend on the processing

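The tests with the GC content and length trend removed and all tests of correlations and of the overlap were chosen only after the data were seen. The matrix list kept its direction under every alternative in the comparisons of free with complete medium under TGF-β1, of BCAA in water, of the BCAA-free diet and of BT2, and so did the bleomycin signature sets. With an estimated correlation the matrix call was lost for BCAA in water (median 0.619, adjusted p = 0.278), the BCAA-free diet (-1.13, adjusted p = 0.102) and BT2 (-1.02, adjusted p = 0.552), as were those of the signature sets with BT2 (-0.43 and 1.08), since a camera test at 0.01 assumes members that vary nearly independently. Counts of changed genes outside 1.5 times the reported one were as follows, and the cause was not tested. With a pseudocount of 0.1, removal of BCAA under PBS gave 40 and BCAA in water 124, and with 0.5 BCAA returned against complete medium gave 0 (262 at an unadjusted p under 0.05 in the reported limma fit). Without a filter, which tests more genes, BCAA returned against complete medium gave 1, BCAA in water 45 and BT2 819. Centring gave 0, 348 and 3315 in the same order. With only the compared groups, and so a spread estimated from these alone, removal under TGF-β1 gave 4795 and BCKA against BCAA 96. BCAA returned against complete medium then gave 0, BCAA in water 38, the BCAA-free diet 1160 and BT2 190. The reported fit pools the spread over all groups of a table. Its p can thus be too small where the compared groups vary more than the others, and too large where they vary less. BLM_DMSO libraries correlated with their own group at 0.943 to 0.945, PBS_DMSO libraries at 0.976 to 0.978. Array weights gave 2611 for removal under PBS, 9926 for the difference of responses, 535 for BCKA against BCAA, 17 for BCAA returned against complete medium, 6265 for bleomycin in the water experiment, 2500 for BCAA in water, 5788 for the BCAA-free diet and 5098 for BT2. With the GC and length trend removed the BCAA-free diet gave 3136 and BT2 3439. With the replicate block BCAA in water gave 64, the only count it moved that far, and 12 of 24 fibroblast, 3 of 9 water, 4 of 12 diet and 5 of 9 BT2 libraries correlated best with their own number, so the labels' numbers were not taken as pairs. The within-experiment correlation for water changed sign with a pseudocount of 0.1 (-0.0742), and Col3a1 with BCKA returned did with array weights (0.199). The depth of the libraries is unknown, so what it limits could not be tested.

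Leaving out each library in turn leaves fewer in its group, with the spread still pooled over all groups. The ranges of changed genes were 5398 to 5944 for TGF-β1, 38 to 88 for removal under PBS and 7322 to 8626 under TGF-β1. They were 5661 to 7430 for the difference of responses, 6877 to 8347 for return of BCAA and 6917 to 8363 of BCKA. For BCKA against BCAA the range was 16 to 26, and for BCAA returned against complete medium 0 to 1. In lungs bleomycin gave 2652 to 3503, 10366 to 11232 and 3334 to 7099 in the water, diet and BT2 experiments, BCAA in water 14 to 591, the BCAA-free diet 908 to 2785 and BT2 138 to 4989. Matrix medians ran from -1.15 to -0.917 for removal under TGF-β1, 0.54 to 0.766 for water, -1.26 to -1.1 for the diet and -1.31 to -0.772 for BT2. Col3a1 with BCKA ran from -0.614 to 0.435. With BCAA returned against complete medium, ribosomal protein genes ran from -0.264 to 0.0292 and oxidative phosphorylation genes from -0.239 to 0.0272. Signature rise and fall sets ran from 0.448 to 0.605 and -0.474 to -0.317 for water, -0.982 to -0.796 and 0.559 to 0.848 for the diet, and -0.671 to -0.309 and 0.875 to 1.43 for BT2. Correlations ran from -0.151 to 0.101 within the water experiment, -0.507 to -0.405 within diet and -0.824 to -0.722 within BT2. Between removal under PBS and return of BCAA they ran from -0.0418 to 0.0113, and of BCKA from -0.0546 to -0.000786. Within the TGF-β1 arm they ran from -0.99 to -0.973 and -0.982 to -0.957. The overlap of both returns ran from 6458 to 7670.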

Other observations

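The correlations repeated without single libraries or with the GC content trend removed, and the genes named in the next paragraph, were chosen only after values were seen.

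The levels of 3 genes differed between the PBS lungs of the experiments. Haem oxygenase 1, Hmox1, was at 4381 ± 624 TPM in PBS_NW lungs (SD, n = 3) and 5464 ± 628 in PBS_DMSO lungs, but at 135 ± 44.2 in PBS_ND lungs (n = 4). The heat shock protein Hspa1b was at 284 ± 20.5, 800.2 ± 193 and 60.6 ± 43.2 TPM, and Chac1, a glutathione-degrading enzyme of the amino acid shortage response, at 68.2 ± 11.9, 76.5 ± 20.5 and 7.31 ± 2.52 TPM in the same order. These levels come from separate tables and were not tested against each other. In fibroblasts under PBS, in groups that entered none of the 14 comparisons once BCAA or BCKA was returned, Acta2 was at 732 ± 34.1 TPM with BCAA and 678 ± 48.5 with BCKA, against 1133 ± 78 in free and 696 ± 12.9 in complete medium. Asns was at 36.6 ± 1.22, 40.7 ± 3.26, 48.3 ± 5.45 and 32.7 ± 2.26 TPM.

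A hypothesis that medium without BCAA weakens the whole response to TGF-β1 was tested on genes that TGF-β1 moved by at least 1 log2 in cells with BCKA returned, so that the set shared no library with either response. For 395 genes that rose, the median response was 1.29 log2 in complete and 0.807 in free medium, smaller in 67.8% of them. For 974 genes that fell it was -1.42 and -1.78, a ratio of 1.26, so a smaller response of all genes is argued against. In the cells with BCKA returned, on which the genes were chosen, the medians were 1.36 and -1.38.

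A hypothesis that treatments move shared genes in bleomycin lungs was tested across experiments, which share no libraries. Across 17562 genes, which are not independent replicates, BT2 and the BCAA-free diet had r = 0.524, and r was 0.56 with the GC and length trend removed, 0.652 without BLM_BCAA_free replicate 3 and 0.519 without BLM_DMSO replicate 1. BCAA in water and the BCAA-free diet had r = -0.565 across 16839 genes, -0.541 with the trend removed and -0.523 without BLM_BCAA_free replicate 3. Water and BT2 had r = -0.472 across 16774 genes. Both signs are consistent with treatments that lie along a shared axis of lung injury, and may come from differences in injury between groups as well as from BCAA, which these data cannot tell apart (0.524 and -0.565 would arise either way).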
